A study of Mus musculus with 4 samples.

How the data were processed

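The data are 4 Affymetrix mouse expression arrays of pooled liver RNA, 1 per group and day, with 2 groups (control; MET deletion plus canertinib, labelled delta MET + EGFRi) and 2 days (7 and 10). Per the submitters' processing notes the values were made with MAS5, whose version is not given in the sources used here. The deposited values are linear intensity (signal) values per probe set, and their mean after trimming 2% at each end was about 500 on each array, as the values themselves show. Detection calls were not used here. The labels do not say how many animals entered a pool, and the 2 arrays of a group are of different days. The p-values of limma for single genes therefore measure the spread between these arrays only, days included. Every column of the value table belonged to a sample of the series. No pair of arrays held more than 0.118% identical values.

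Of 45101 probe sets 64 were array controls. Of the remaining 45037, the platform annotation gave 34945 a single gene symbol, 932 several and 9160 none, and those with several or none entered no gene count. Symbols were looked up by Entrez ID in the RefSeq gene table of assembly GRCm38.p6, used for names only, in which 99.4% of the singly named probe sets matched and 0 symbols had to be updated. No genome coordinates were used. Signals under the 25th percentile of all values (64.8) were set to it, log2 was taken, and each of 18194 genes was represented by its brightest probe set. The 11993 genes with a mean log2 above the median of all probe sets (7.67, a signal of 204) were kept. A gene at or under the floor on every array of a group has only a bound there, and its fold is given as "at least".

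The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend; two-sided; Benjamini-Hochberg adjusted p under 0.05), with 2 arrays per group, no day term and 2 residual degrees of freedom per gene. Log2 differences are treated minus control, with limma's SE. Single days and days within a group have 1 array per side and were described by a 2-fold size rule without a test. In all, 46 gene lists were fixed before the data were examined, as were the groups, the tests and the alternatives. Lists with at least 5 kept genes were tested with limma's camera at the preset correlation of 0.01, with an estimated correlation, and with fry, and adjusted over the 42 lists tested. A list's median at each day was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. Such a percentile comes from 1 array per group, treats a list's genes as independent and is not a p-value. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

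The genes named were chosen by a rule fixed beforehand: Met, Egfr, Erbb2 and Erbb3; the 10 highest and 10 lowest genes by the smaller of their 2 daily differences among genes that pass and are at least 2-fold apart at both days, passing over predicted genes; up to 4 members of each list with the same sign at both days; and the 5 highest and 5 lowest genes by the difference between the effects at day 10 and day 7. Erbb2 lay under the filter on dim genes.

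The limma and camera steps were tested on simulated arrays with the means of the 11993 kept genes, 200 of them changed, in 10 runs. Each gene's spread was drawn from the distribution that limma fitted to the real arrays. The noise was normal, and no day difference or floor was put in. For this comparison of 2 against 2 arrays, 3.75% of 2-fold changes were recovered, 61% of 4-fold, 78.8% of 8-fold, 83.8% of 16-fold and 85.8% of 32-fold changes, 3.69% of the calls were false, and runs without any change gave 0 calls. A list shifted by design was called up in 10 of 10 runs, at an unadjusted p under 0.05. Genes were simulated as independent, whereas the estimated correlation was 0.51 in the acute phase and 0.79 in the macrophage list. The runs therefore do not show how often false calls arise among correlated genes. Since the spread was drawn from the model that limma assumes, a low share of false calls follows largely from the construction. It does not measure false calls on the real arrays.

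Alternatives were quantile normalization, arrays scaled to equal medians, a floor at the 10th or 40th percentile, no filter or a filter at the 75th percentile, the mean of a gene's probe sets, limma without the trend, day as a block, leaving out each array in turn, an adjusted p under 0.1, size rules of 1.5-fold and 3-fold, the estimated correlation, fry, and each other probe set of a named gene. Leaving out an array left 1 array in its group, so that the spread came from the other group alone, which limits such p-values. Chosen after seeing the data were the acute phase and neutrophil lists without their shared gene Lcn2, and counts of probe sets with no or several gene symbols.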

Results

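Liver gene expression was measured on 4 single-colour Affymetrix mouse arrays. The mice carried a Met gene flanked by recombination sites and a Cre recombinase that tamoxifen switches on. Tamoxifen was injected on 5 days to remove exon 16 of Met, the receptor of hepatocyte growth factor. After 4 days of rest the mice ate a diet with canertinib, an inhibitor of the epidermal growth factor receptor (EGFR), aimed at 80 mg/kg/day. The labels call this group delta MET + EGFRi, and it is named the treated group here. Control mice received corn oil, with neither tamoxifen nor canertinib, so that the effects of Met deletion, tamoxifen, canertinib and any change in feeding are not separated here. Livers were taken at day 7 and day 10, which for treated mice the labels count from the start of canertinib in the diet. The RNA of each group and day was pooled on 1 array, so that each group has 2 arrays. The 2 treated arrays thus also differ in the length of canertinib feeding. The median signal ranged from 210.5 to 223.9 over the 4 arrays. Log2 signals of pairs of arrays correlated across probe sets with r from 0.923 to 0.948, the highest r being that of the 2 control arrays. The number of arrays limits the precision of every value, and pooled RNA carries no spread between animals.

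The first comparison asked which liver genes differed between the treated and the control group over both days. In the treated livers the metal-binding metallothioneins Mt1 and Mt2 and the acute phase genes Lcn2, Orm2, Saa2 and Saa3 rose, while carbonic anhydrase Car3, the steroid dehydrogenase Hsd3b5, the fatty acid elongase Elovl3 and the iron hormone gene Hamp (hepcidin) fell. Mt1 rose 56.0-fold, from 1006 ± 74.6 to 57961 ± 19967 signal units (mean ± SD, n = 2 arrays per group), and Lcn2, an iron-scavenging secreted protein, rose 116-fold (40.6-fold at day 7 and 332-fold at day 10). Car3 fell 185-fold, from 48576 ± 8114 to 273 ± 116 units (n = 2), and Elovl3 fell 51.3-fold. Hamp fell 24.5-fold, from 53006 ± 4026 to 2177 ± 370 units (n = 2), and Hamp2, similar in sequence, fell 23.1-fold.

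In limma's test over 11993 kept genes, 45 genes rose and 34 fell at a Benjamini-Hochberg adjusted p under 0.05, and 1449 genes had an unadjusted p under 0.05. Each of these 79 genes was at least 2-fold apart in its direction at both days. A call already needs a large mean difference and a small spread between the days, so that this is no separate check. The adjusted p of Mt1 was 0.000928 and that of Lcn2 0.0132, and another probe set of Mt1 gave a log2 difference of 3.73 that did not pass (adjusted p = 0.164), against 5.81 for the brightest. Mt2 rose 40.7-fold (adjusted p = 0.00128) and the interleukin 1 receptor Il1r1 20.8-fold (adjusted p = 0.00128). Orm2 rose 55.5-fold (adjusted p = 0.0231), Saa2 38.5-fold (adjusted p = 0.0216) and Saa3 18.0-fold (adjusted p = 0.000928). Orm2 was 18.8-fold higher at day 7 and 164-fold at day 10, and Saa2 14.6-fold and 101-fold. Without the day 10 control array the log2 differences of Orm2 and Saa2 were 4.83 and 4.52 and neither passed (adjusted p = 0.0897 and 0.123). The control signals of 3 further genes lay at or under the floor of 64.8 on both arrays. The neutrophil protease gene Prtn3 was at least 40.8-fold higher (adjusted p = 0.013; at least 23.8-fold at day 7 and 70.1-fold at day 10), Acnat2 at least 21.2-fold (adjusted p = 0.00337) and the immunoglobulin segment Igkv8-30 at least 18.4-fold (adjusted p = 0.00501). Among the 10 lowest, Hsd3b5 lay at the floor on both treated arrays and was at least 138-fold lower (adjusted p = 0.000397). Sult2a8 fell 20.4-fold, the fatty acid hydroxylase Cyp4a12a 20.2-fold and the major urinary protein gene Mup10 18.1-fold. Hsd3b2 fell 12.7-fold and Scd1, which makes monounsaturated fatty acids, 13.5-fold. The adjusted p of these 5 genes ranged from 0.00102 to 0.0144. The within-group spread includes any change from day 7 to day 10. All 79 calls were lost when dim genes were not filtered out (0 of 18194 genes by limma, with 1918 at an unadjusted p under 0.05 and 1409 constant within both groups after flooring). The count was 42 without the intensity trend, 42 with the mean of a gene's probe sets, 47 with day as a block, 26 without the day 7 control array, 24 without the day 10 control array, 466 without the day 7 treated array and 330 without the day 10 treated array. The fits without a treated array took their spread from the control arrays alone. Of the named genes, Orm2, Saa2, Gclc, C1qc, Vsig4, Icam1 and Cebpb did not pass with day as a block, at adjusted p from 0.0518 to 0.118. Without the trend S100a9 and the same 7 genes did not pass, and with the mean of probe sets Mt1, Orm2, Saa2, Cebpb, Cyp51, C1qc, S100a9 and Icam1 did not. Leaving out either control array ended the calls of Prtn3, Hsd3b2, Scd1, Cebpb, Igfbp1, Cyp51, Acaa1b, Gclc, Cyp17a1, Cd163, C1qc, Vsig4 and Icam1, and leaving out that of day 7 ended the call of S100a9.

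**Figure D1:**
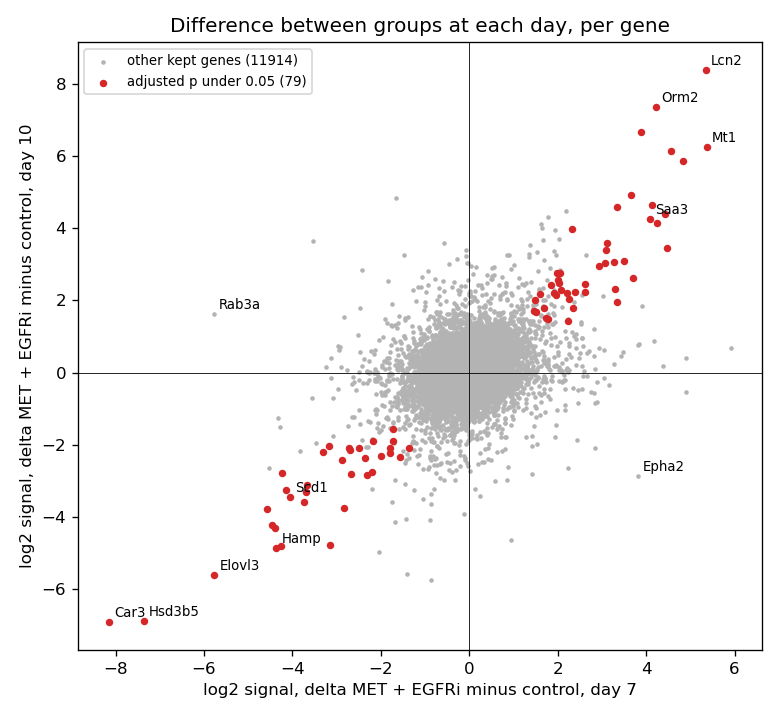
Each point is a gene, with the log2 signal difference between the treated and the control array at day 7 on the horizontal axis and at day 10 on the vertical axis. The 79 genes with an adjusted p under 0.05 (red) lie in the upper right and lower left, from Lcn2 (5.34 and 8.37) to Car3 (-8.15 and -6.91).

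**Figure D2:**
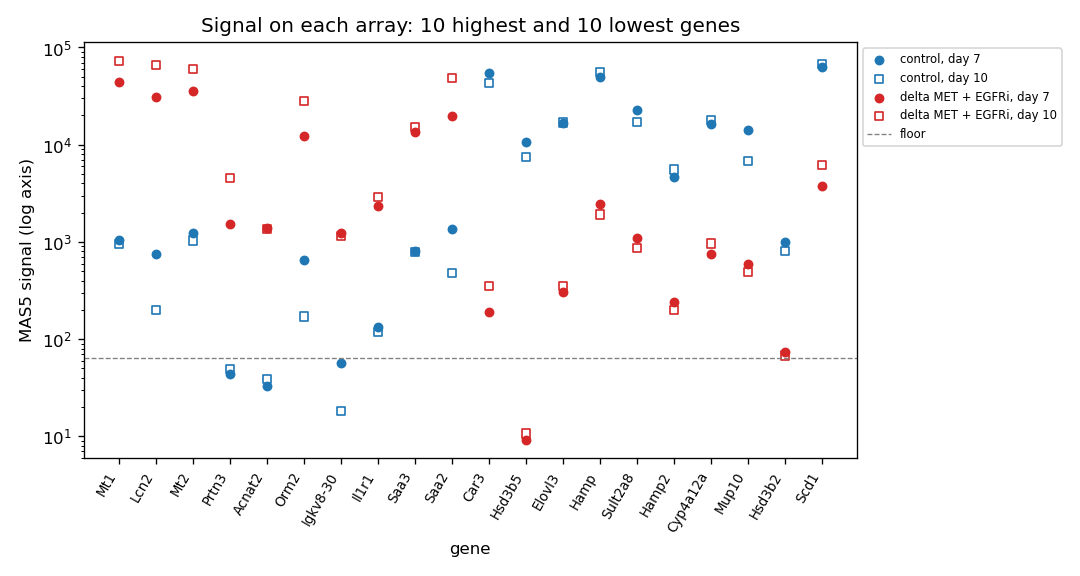
MAS5 signal on each of the 4 arrays, on a log axis, for the 10 highest and the 10 lowest named genes, with control arrays in blue, treated arrays in red, day 7 as filled circles, day 10 as open squares and the floor of 64.8 as a dashed line. For each gene both treated arrays lie on the same side of both control arrays, which the rule that picked these genes favours.

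Met itself was not lower in the treated livers. Its signal was 1123 ± 209 units in control and 2631 ± 280 in treated livers (SD, n = 2), a log2 difference of 1.24 ± 0.23 (SE) that did not pass the test (adjusted p = 0.103). Without the day 7 treated array the log2 difference was 1.345. The positions of the probes relative to the deleted exon 16 were not used here, and a probe set outside it does not check the deletion. Egfr differed by -0.05 ± 0.30 (adjusted p = 0.969) and its partner receptor Erbb3 by 0.32 ± 0.21 (adjusted p = 0.601), and Erbb2 lay under the filter on dim genes. Of 13 kept genes for the receptors, their ligands and adaptors, 0 passed over all genes and 1 was higher when adjusted over the list alone. The list's median log2 difference was 0.09 (camera adjusted p = 0.777). Of 16 genes of ERK feedback and the immediate-early response, 0 passed over all genes, and 2 were higher and 1 lower when adjusted over the list alone. Their median was -0.01 against a mean of 0.32 (camera adjusted p = 0.416). Among them Junb was higher at day 7 and day 10 by 1.63 and 4.00 on the log2 scale, and the cell cycle gene Ccnd1 lower, at -1.17 and -0.68.

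The second question was whether groups of genes fixed before the data were examined moved together. Of 46 lists, 42 held enough kept genes for a test, and limma's camera with its preset correlation called 12 up and 5 down. At the preset, camera sets a list's genes against all other genes and takes them as nearly independent replicates. Its p-values there rest mainly on the spread between genes, not between arrays. The estimated correlation was 0.79 in the macrophage and 0.51 in the acute phase list, over the preset 0.01, and under it in some other lists. With an estimated correlation 0 of the 42 were called, at adjusted p from 0.583 to 0.996. These p-values rest on the 2 residual degrees of freedom per gene, which leave little power to call any list. Lists with an estimated correlation under the preset 0.01, such as neutrophil markers (-0.070) and chemokines (-0.080), lost their call too. A call lost in this setting therefore does not show that correlation between genes explains it. The fry test, which asks whether a list's genes move one way on balance, called coagulation factors and male-biased genes (adjusted p = 0.0487 for both).

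Camera at its preset correlation called the acute phase, macrophage, neutrophil and chemokine lists up. Of 23 acute phase genes 11 rose and 1 fell, and 20 rose and 1 fell when adjusted over the list alone. The median log2 difference was 1.79 at day 7 and 3.40 at day 10, both at percentile 100 of matched random lists (camera adjusted p = 8.22e-26, and adjusted p = 0.583 with an estimated correlation). The member that fell was Hamp. Of 14 macrophage and Kupffer cell markers 3 rose, and 10 when adjusted over the list alone. The haemoglobin scavenger receptor Cd163 rose 7.72-fold, the complement component C1qc 4.83-fold and Vsig4 4.14-fold, the last 2 not passing with day as a block (adjusted p = 0.0518 for both). The list's median was 0.94 at day 7 and 1.52 at day 10 (camera adjusted p = 9.47e-11, and adjusted p = 0.583 with an estimated correlation). Of 10 neutrophil markers 3 rose, and 4 when adjusted over the list alone. The 3 were Lcn2, which the acute phase list also holds, S100a8 (10.2-fold) and S100a9 (8.97-fold). The list gave camera adjusted p = 5.07e-05, and adjusted p = 0.583 with an estimated correlation. Of 10 chemokine and cytokine genes 1 rose, and 4 when adjusted over the list alone. The adhesion molecule Icam1 rose 3.08-fold (adjusted p = 0.118 with day as a block), and the neutrophil attractant Cxcl1 was 5.28-fold higher without passing (adjusted p = 0.064, but 0.0442 with arrays scaled to equal medians). The log2 difference of Cxcl1 was 2.96 without the day 7 and 1.84 without the day 10 treated array. Camera gave adjusted p = 0.000639, and adjusted p = 0.583 with an estimated correlation.

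Other immune and stromal lists gave no call as reported, though some did in other settings. Among 9 B and plasma cell markers 1 rose, the antibody joining chain Jchain (9.83-fold), and 2 rose when adjusted over the list alone. The brightest probe sets of Ighm and Igha did not pass. In a limma fit over the probe sets above the filter, another of Ighm (log2 difference 2.39, adjusted p = 0.0368) and others of Igha (3.35 and 3.72, adjusted p = 0.0379 for both) passed. The list's median was -0.03 against a mean of 0.61 (camera adjusted p = 0.142). Without the day 7 control array the median was 0.12 and the adjusted p 0.0412. None of the 6 T and NK cell markers passed over all genes or when adjusted over the list alone (camera adjusted p = 0.862). Of 13 interferon response genes 0 passed over all genes, and 1 was higher and 1 lower when adjusted over the list alone. The median was -0.64 (camera adjusted p = 0.0622, and 0.046 when the arrays were scaled to equal medians). The interferon list was also called down with day as a block (adjusted p = 0.0446) and with the mean of probe sets (0.0304). It was called down without the day 10 control array (median -0.96, adjusted p = 0.00462) and without the day 10 treated array (-0.48, adjusted p = 0.0264). Stellate cell and matrix genes had a median of -0.01 and a mean of 0.09 over 19 genes (camera adjusted p = 0.416), with 0 passing, and 1 higher when adjusted over the list alone. The brightest probe set of Fn1, in this list, did not pass, but another did by limma (log2 difference 1.94, adjusted p = 0.0456). The 13 sinusoidal endothelial markers had a median of 0.19 (camera adjusted p = 0.162), with 0 passing, and 0 when adjusted over the list alone. Without the day 7 treated array their median was 0.41 and the list was called up (adjusted p = 0.00978). The 5 cholangiocyte and progenitor markers and the 7 fetal liver genes share Cd24a, which was 3.42-fold higher (adjusted p = 0.0534, and 0.0464 with arrays scaled to equal medians). In each of these lists 0 passed over all genes and 1 was higher when adjusted over the list alone. Camera gave adjusted p = 0.637 for the cholangiocyte list, whose median was -0.02 and mean 0.03, and 0.394 for the fetal list.

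At the preset correlation the cholesterol list was called up and the fatty acid synthesis and oxidation lists down. Of 20 genes of cholesterol synthesis and uptake 1 rose, the sterol demethylase Cyp51 (4.61-fold, adjusted p = 0.0144), and 10 rose when adjusted over the list alone. Further probe sets of Cyp51 gave smaller log2 differences, 1.27 and 0.75, that did not pass, against 2.20 for the brightest. The list's median was 0.91 at day 7 and 1.27 at day 10 (camera adjusted p = 4.6e-09, and adjusted p = 0.583 with an estimated correlation). Of 18 genes of fatty acid and triglyceride synthesis 1 fell, Scd1, and 5 fell when adjusted over the list alone. At both days 16 of them were lower, with medians of -1.10 and -0.34 (camera adjusted p = 2.14e-07, and adjusted p = 0.583 with an estimated correlation). Among 19 genes of fatty acid oxidation and PPARA targets 1 fell, the peroxisomal thiolase Acaa1b (15.7-fold), and 3 when adjusted over the list alone. Camera gave adjusted p = 0.0481, and adjusted p = 0.661 with an estimated correlation. Without the day 10 control array the adjusted p was 0.516, and without the day 7 treated array 0.0986. It was 0.0904 with the filter at the 75th percentile and 0.115 without a filter. Lipoprotein genes showed no call (camera adjusted p = 0.2 over 12 genes), with 0 passing and 3 higher when adjusted over the list alone. Among them Apoa4 was 3.68-fold higher (adjusted p = 0.0917), with a log2 difference of 2.365 without the day 7 and 1.395 without the day 10 treated array.

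Of 10 male-biased liver genes 5 fell, and 8 when adjusted over the list alone. The 5 were Hsd3b5, Elovl3, Cyp4a12a, the organic anion carrier Slco1a1 (11.3-fold) and the glucuronosyltransferase Ugt2b38 (log2 difference -3.38), the last named after its value was seen. The median was -3.57 at day 7 and -2.52 at day 10 (camera adjusted p = 2.84e-15, and adjusted p = 0.583 with an estimated correlation). Of 7 female-biased genes 1 rose, the steroid hydroxylase Cyp17a1 (15.5-fold), and 1 when adjusted over the list alone. Camera gave adjusted p = 0.0382, adjusted p = 0.583 with an estimated correlation, 0.0584 without the day 7 control array, 0.0518 with the mean of probe sets and 0.222 without a filter. Of the 4 sex-linked genes, too few for a test, 0 passed over all genes or when adjusted over the list alone, and the medians were 0.23 and 0.13. Among 12 genes of the growth hormone and IGF axis 1 rose, the insulin-repressed binding protein Igfbp1 (8.98-fold), and 1 was higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.416). The list's median was 0.12, and without the day 10 treated array it was 0.39 and the list was called up (adjusted p = 0.025).

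The NRF2 and glutathione and the oxidative phosphorylation lists were called down. Of 17 NRF2 and glutathione genes 1 fell, Gclc (4.47-fold, adjusted p = 0.0518 with day as a block), the catalytic subunit that limits glutathione synthesis, and 6 fell when adjusted over the list alone. At both days 10 of the 17 were lower and 2 higher, with medians of -0.65 and -0.72 (camera adjusted p = 0.00268, adjusted p = 0.661 with an estimated correlation, and 0.159 without a filter on dim genes). For oxidative phosphorylation 21 of 23 genes were lower at both days, and 0 passed over all genes or when adjusted over the list alone. The median was -0.40 (camera adjusted p = 7.38e-06, and adjusted p = 0.583 with an estimated correlation). Cytosolic ribosomal protein genes were higher, with 13 of 15 higher at both days and a median of 0.36. Over all genes 0 passed, and 0 when adjusted over the list alone (camera adjusted p = 0.000151, and adjusted p = 0.583 with an estimated correlation).

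Among 16 hepatocyte transcription factors 1 rose, Cebpb (2.98-fold), and 1 when adjusted over the list alone. Cebpb did not pass with day as a block (adjusted p = 0.116), nor did its other probe set (log2 difference 0.98, adjusted p = 0.222) or the mean of its probe sets (1.28, adjusted p = 0.0923), against 1.58 for the brightest. Camera gave adjusted p = 0.0382, and adjusted p = 0.583 with an estimated correlation. Without the day 7 control, the day 10 control and the day 7 treated array the adjusted p was 0.0957, 0.0844 and 0.0509. It was 0.0706 with the mean of probe sets, 0.0533 with the filter at the 75th percentile and 0.052 without a filter. Of 18 coagulation factors 0 passed over all genes and 1 was higher when adjusted over the list alone. The median was 0.33 (camera adjusted p = 0.0108, and adjusted p = 0.583 with an estimated correlation). Without the day 7 and the day 10 control array the adjusted p was 0.0848 and 0.0611, and without a filter 0.119. Hepatocyte plasma proteins were called up at a median of 0.06 over 16 genes (camera adjusted p = 0.0382, and adjusted p = 0.661 with an estimated correlation). Of these genes 0 passed over all genes and 1 was higher when adjusted over the list alone. Under quantile normalization the median turned to -0.07, and the call also ended with day as a block (adjusted p = 0.0636), the mean of probe sets (0.077), the filter at the 75th percentile (0.0533) and no filter (0.133). Leaving out the day 7 control, the day 10 control or the day 7 treated array ended that call (adjusted p = 0.249, 0.0844 and 0.308), the last with a median of -0.04. Among 15 complement genes made by hepatocytes 0 passed over all genes and 3 were lower when adjusted over the list alone (camera adjusted p = 0.0828, 0.0493 under quantile normalization and 0.0398 without the day 7 treated array). The circadian clock list was called up (camera adjusted p = 0.0483, and adjusted p = 0.583 with an estimated correlation), with 0 of 13 genes passing over all genes or when adjusted over the list alone. The adjusted p was 0.177 without the day 7 control and 0.338 without the day 7 treated array. It was 0.47 with the filter at the 75th percentile, 0.077 with the mean of probe sets and 0.162 without a filter. Unfolded protein and stress response genes were called up (camera adjusted p = 0.0297, and adjusted p = 0.661 with an estimated correlation), with 0 of 20 passing over all genes or when adjusted over the list alone. The adjusted p was 0.106 without the day 7 control array, and without the day 10 treated array it was 0.902 at a median of -0.06. It was 0.0986 with the filter at the 75th percentile and 0.119 without a filter.

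The other metabolic and growth lists gave no call as reported. Among 12 fasting and insulin-responsive genes 1 rose, Igfbp1, and 3 were higher and 2 lower when adjusted over the list alone. The median was -0.05 and the mean 0.34 (camera adjusted p = 0.437). Glycolysis (camera adjusted p = 0.327 over 11 genes), the pericentral zone (0.0759 over 13 genes) and autophagy and lysosome genes (0.0742 over 15 genes) each had 0 genes passing over all genes and 1 higher when adjusted over the list alone. The pericentral list, with a median of 0.23, was called up without the day 7 control array (0.47, adjusted p = 0.0368) and without the day 10 treated array (0.43, adjusted p = 0.000347). Autophagy and lysosome genes were called up without the day 10 treated array (adjusted p = 0.00168). For p53 targets and cell cycle arrest, 0 of 13 genes passed over all genes, and 2 were higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.3). Gadd45g, at a log2 difference of 2.95 (adjusted p = 0.0865), passed with day as a block (0.0287). Its log2 difference was 3.69 without the day 7 and 2.22 without the day 10 treated array. Of 14 cell cycle genes 0 passed over all genes, and 0 when adjusted over the list alone. Camera's direction for them was up at a median of -0.09 and a mean of -0.01 (adjusted p = 0.995). Lists of other tissues were too short for a test. The 2 erythroid genes were lower at both days, with a median of -0.52 at day 10, and 0 passed, with 1 lower when adjusted over the list alone. The 4 pancreatic acinar genes had medians of -0.31 and 0.23, with 0 passing, and 0 when adjusted over the list alone. The 2 skeletal muscle and fat genes had medians of 0.10 and 0.56, with 0 passing, and 1 higher when adjusted over the list alone.

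**Figure D3:**
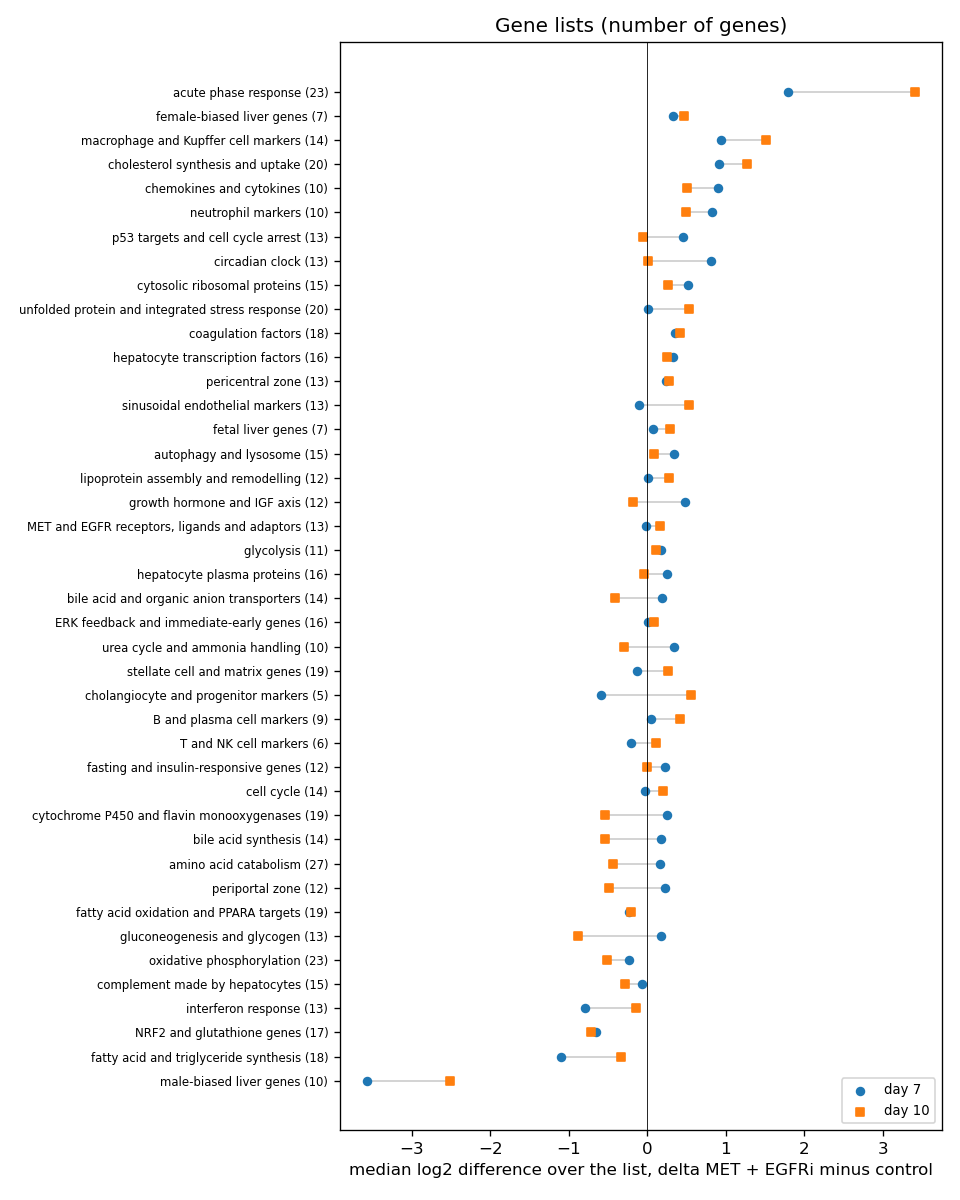
Median log2 difference between the treated and the control array over each tested gene list, at day 7 (blue circles) and day 10 (orange squares), with the number of kept genes in parentheses. Acute phase genes lie farthest to the right (1.79 and 3.40) and male-biased genes farthest to the left (-3.57 and -2.52), and several metabolic lists lie on opposite sides of 0 at the 2 days.

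The third comparison set the groups against each other at day 7 alone, with 1 array on each side and so no test. Cyp4a14, a fatty acid hydroxylase, was 60.3-fold higher in the treated pool at day 7, the deubiquitinase Usp2 29.8-fold higher, and the clock gene Per1 higher by 3.82 on the log2 scale, while the fatty acid binding protein Fabp1 was lower, at -4.33. In all, 552 genes were at least 2-fold higher and 619 at least 2-fold lower. The circadian clock list had its larger shift here, a median of 0.81 at the 100th percentile of matched random lists, against 0.01 at day 10.

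At day 10 alone, also without a test, the uridine phosphorylase Upp2 was 24.9-fold lower in the treated pool. The glutathione transferase Gsta2 was lower, at -5.58 on the log2 scale, and so was Cyp8b1, which sets the share of cholic acid among bile acids, at -4.97. At least 2-fold differences were seen in 700 genes higher and 589 lower. Gluconeogenesis and glycogen genes had a median of -0.88 at day 10 (percentile 0.01 among matched random lists) against 0.18 at day 7. These percentiles treat genes as independent and carry no spread between arrays, while this list's estimated correlation was 0.38. Cytochrome P450 and flavin monooxygenase genes had -0.54 (percentile 0.81) against 0.25, and bile acid synthesis genes -0.54 (percentile 0.91) against 0.17. Amino acid catabolism genes had -0.44 (percentile 2.32) against 0.16, and bile acid and organic anion transporters -0.41 (percentile 2) against 0.19. Periportal genes had -0.49 (percentile 3.76) against 0.23, and urea cycle genes -0.30 (percentile 19.7) against 0.35. Over both days together camera called 0 of these 7 lists, at adjusted p = 0.103, 0.612, 0.38, 0.437, 0.25, 0.3 and 0.658 in that order. Without the day 7 treated array the first 6 of them were called down, and without the day 10 treated array the P450, amino acid and urea cycle lists were called up (adjusted p = 0.0269, 0.00811 and 0.0201). Of the transporters 1 fell, Slco1a1, and 0 members of the remaining lists passed over all genes. When adjusted over the list alone, 1 gluconeogenesis gene was higher and 4 were lower, 3 transporters were lower, and 1 urea cycle gene was higher and 1 lower. In the other 4 of these lists 0 passed when adjusted over the list alone. The transporter list had a median of 0.01 and a mean of -0.27 over both days, and the urea cycle list -0.01 and 0.02.

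At both days in the same direction, 185 genes were at least 2-fold higher and 137 at least 2-fold lower in the treated livers, Mt1, Lcn2, Car3 and Elovl3 among them. The other ways to pair the 4 arrays gave fewer: 24 genes higher and 33 lower at day 10 than at day 7 in both groups, and 34 and 47 in the crossed pairs. By limma these pairings called 0 genes each, with 184 and 306 genes at an unadjusted p under 0.05. These fits had no group term, so that differences between the groups entered their spread and lowered their counts. They therefore do not show how many genes limma would call without a treatment effect. Across genes, which are not independent replicates, the differences at the 2 days correlated with r = 0.348, and 57.8% of genes had the same sign at both days.

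Within each group, day 10 was set against day 7 without a test. Rab3a, a vesicle GTPase, had a signal of 8541 at day 7 and 1240 at day 10 in control livers, against 156 and 3796 in treated livers, and the ephrin receptor gene Epha2 had 78.6 and 546.6 against 1108 and 74.9. In control livers 246 genes were at least 2-fold higher at day 10 than at day 7 and 370 lower, and in treated livers 460 were higher and 453 lower. Whether the number of genes that differ between days is itself different between the groups was not tested.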

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

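The tests of Y-linked, plasma protein, growth hormone target, erythroid, T and NK cell and clock genes and of the actin ratio were chosen only after the result was seen. The test of pan-leukocyte genes was written after the acute phase and macrophage result was seen, but before the values of its own genes were read. The differences between days listed here rest on 1 array per group and day and were not tested.

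Male-biased liver genes were lower in the treated livers, with medians of -3.57 at day 7 and -2.52 at day 10. Pools of different sex make-up would lower Y-linked genes as far, but the lower of the daily medians of Eif2s3y, Kdm5d and Uty was 0.10. A lower share of hepatocytes would lower the plasma protein genes as far, and the lower of their medians was -0.047. The highest signal among these genes was 82540, and whether signals that bright show a fall in full was not tested. Weaker growth hormone signalling stays open: the higher daily median of Igf1, Igfals, Socs2, Cish and Ghr was 0.22, with members on both sides of 0. Met deletion, tamoxifen, canertinib and any change in feeding were not separated by the design and stay open too.

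Acute phase and macrophage genes were higher, at 1.79 and 3.40 for the acute phase list. More myeloid cells in the liver would raise pan-leukocyte genes. These, without Tyrobp, had a lower daily median of 0.76, and all 7 kept ones were higher at both days. None of them passed by limma (adjusted p from 0.122 to 0.472). They mark leukocytes of every kind and come from the same arrays, whose macrophage genes were already seen to be higher. They go with more myeloid cells but do not set these apart from other leukocytes. Blood left in the tissue would raise erythroid genes, whose higher median was -0.52, but with 2 kept genes this decides nothing. More leukocytes of every kind would raise T and NK cell markers, whose higher median was 0.11 with a spread of 0.32, and stays open. Such a spread is scaled from the standard error over a list's genes. It treats genes as independent and holds no spread between arrays or animals. A change within resident macrophages was not tested.

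Several metabolic lists had medians of opposite sign at the 2 days, by at least 0.5: gluconeogenesis and glycogen (day 10 minus day 7, -1.06), cytochrome P450 and flavin monooxygenases (-0.79), bile acid synthesis (-0.71), the periportal zone (-0.71), the urea cycle (-0.65), bile acid and organic anion transporters (-0.61) and amino acid catabolism (-0.59). Degraded RNA on the day 10 treated array would give it the highest ratio of 3' to 5' actin signal, but its 1.98 lay under the 2.59 of the day 10 control array, and its Gapdh ratio of 1.09 under the 1.22 of the day 7 treated array. A lower share of hepatocytes at day 10 would lower plasma protein genes as far, and their median change was -0.23 against at least 0.57 in size for these lists without the periportal zone, with -0.04 for coagulation factors. The limit given above for bright plasma protein signals holds here too. Another time of day at harvest stays open: the negative and positive arms of the clock parted by 1.05 (spread 0.985) at day 7 and -0.60 (spread 0.239) at day 10, a change of -1.65. These spreads are over genes as well, with 2 kept genes in the positive arm. The bound set for this test looked for a parting at day 10 alone, which was wrong, since a parting at day 7 would change the day 7 medians as well.

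Among the other tested lists, those with opposite medians at least 0.5 apart were the growth hormone and IGF axis (-0.66), p53 targets and cell cycle arrest (-0.51), cholangiocyte and progenitor markers (1.15) and sinusoidal endothelial markers (0.63). Single genes at least 2-fold apart in opposite directions at the 2 days were Rab3a (effect at day 10 minus day 7, 7.39 on the log2 scale), Mroh2a (7.18), Nlrp12 (6.502), Derl3 (5.28), Shh (4.74), Epha2 (-6.68) and Spaca4 (-4.94). Over all kept genes, 21 were at least 2-fold higher at day 7 and lower at day 10, and 36 the other way. Among probe sets outside the gene counts, 45 with no gene symbol were at least 2-fold higher and 32 lower in treated livers at both days, of 3044 above the filter, and 13 and 11 of 552 with several symbols.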

How the results depend on the processing

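The acute phase and neutrophil lists without Lcn2 were an alternative chosen after seeing the data. Their medians were 2.45 and 0.49, and both stayed called by camera at the preset correlation (adjusted p = 3.72e-24 and 0.00118). They were not run with an estimated correlation, at which the full lists were not called (adjusted p = 0.583 for both). Quantile normalization, equal medians and floors at the 10th and 40th percentile kept all gene counts within 1.5 times, and the share of higher among passing genes was 57% as reported, 51.6% under quantile normalization, 54.5% under equal medians, 65.4% without the day 7 control array and 42.3% without the day 7 treated array, where more genes fell than rose. The 34 passing named genes have 0 further probe sets of opposite sign, while 12 of all 188 named genes have at least 1. The causes of the moves below were not tested, apart from what fewer or more genes, arrays or a looser threshold bring by construction. Without a filter on dim genes limma called 0 genes higher and 0 lower (1918 of 18194 at an unadjusted p under 0.05; without the trend also 0, and 2231), and the signals of 1409 of these genes were constant within both groups. Then 1101 genes were at least 2-fold higher and 1236 lower at day 7, 1346 and 1130 at day 10, and 321 and 254 at both days. Between days there were 697 higher and 901 lower in control and 1037 and 948 in treated livers, and camera called 6 lists up and 3 down. With the filter at the 75th percentile the counts were 295 and 243 at day 7, 322 and 310 at day 10, 114 and 80 at both days, 73 and 91 between days in control and 169 and 207 in treated livers, with 7 lists up. With the mean of a gene's probe sets 22 genes rose and 20 fell, and 160 were higher at day 10 in control livers. Without the trend 23 rose and 19 fell, with day as a block 24 rose, and at an adjusted p under 0.1, 93 rose and 69 fell. A 1.5-fold rule gave 1449 higher and 1841 lower at day 7, 1749 and 1618 at day 10, 492 and 498 at both days, 870 and 1146 between days in control and 1508 and 1259 in treated livers. A 3-fold rule gave 213 and 193 at day 7, 246 and 197 at day 10, 71 and 46 at both days, 76 and 124 in control and 132 and 152 in treated livers. With an estimated correlation 0 lists were called up and 0 down, and by fry 1 up and 1 down. Leaving out each array in turn, where the lone array is assumed to vary like the other group, gave 13 to 197 genes that rose, 9 to 269 that fell, 8 to 17 lists up and 5 to 11 lists down. The lowest number that rose came without the day 10 control array and the highest without the day 7 treated array, which also gave the 11 lists down. Hepatocyte plasma proteins turned to -0.070 under quantile normalization. Over the arrays left out, list medians ranged from -0.041 to 0.22 for hepatocyte plasma proteins, from -0.12 to 0.27 for B and plasma cell markers, from -0.36 to 0.22 for bile acid and organic anion transporters, from -0.25 to 0.34 for the urea cycle, from -0.49 to 0.20 for amino acid catabolism, from -0.66 to 0.24 for cytochrome P450 genes and from -0.056 to 0.59 for the unfolded protein response. Signals near the floor limit what can be said of dim genes, and no detection calls were used.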

Other observations

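The genes named in this paragraph, all of which passed and are in no list, were chosen after their values were seen. The BMP-SMAD and glucocorticoid tests below were written after the results that they address were seen. The values of the genes that they use had not been read by then. The zinc importer Slc39a14 rose by a log2 difference of 2.38, the ferritin receptor Scara5 by 2.25, and the NF-kB regulators Nfkbiz and Tnfaip3 by 2.81 and 2.30. Il18bp, a soluble interleukin 18 antagonist, rose by 3.96 and the transcription factor gene Cebpd by 2.06. Carboxylesterases Ces1f and Ces2e fell by 2.74 and 2.75, the aldehyde oxidase Aox3 fell by 2.37, the succinate receptor Sucnr1 fell by 3.69 and the water channel Aqp8 fell by 2.59.

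Hepcidin fell while other acute phase genes rose, and a candidate explanation is lower BMP-SMAD signalling in hepatocytes. Other targets of this pathway, without Hamp and Id3, had medians of -0.88 at day 7 and -1.02 at day 10, and the higher was -0.88. All 4 kept ones (Id1, Id2, Smad6 and Smad7) were lower at both days, Smad6 by only 0.41 and 0.08. By limma 0 of the 4 passed, Id2 lying closest (log2 difference -1.39, adjusted p = 0.0504). This explanation came from the same arrays that tested it.

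Fkbp5 and Zbtb16, which glucocorticoids induce, rose by 2.64 and 1.84 on the log2 scale, and a glucocorticoid response was a candidate explanation. Other genes that glucocorticoids induce, Tsc22d3, Sgk1 and Klf9, had a median of 0.79 at day 7 but -0.42 at day 10, without the predicted rise at both days. Klf9 alone stayed higher at day 10, by 0.12. Per1, Cebpd, Tat and Gadd45b were left out because their values had been seen. Of these, Per1 (3.82 and 0.77) and Cebpd (2.35 and 1.78) were higher at both days, and daily values of Tat and Gadd45b are not given here. With 3 genes and 1 array per group and day, the test does not decide on a response at both days. A response at day 7 alone was not tested separately.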
